A study of Mus musculus with 2 samples.

How the data were processed

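DNase-seq, which maps open chromatin by where the enzyme DNase I cuts, was measured in the gastrocnemius (calf muscle) of male adult mice of the F1 hybrid B6CASTF1/J, aged 18 to 20 months. Per the labels there were 2 samples in 1 group, 2 biological replicates with technical replicate 1 each. Both samples carry the same donor label and different biosample labels, so whether they come from 1 animal is not known, and an SD with n = 2 is the spread between these 2 samples. No contrast, control or other age was given, so no difference between groups was tested and no p-value is reported. Comparisons were made between replicates, between gene lists and random lists within each replicate, and between footprints and control windows. No paired analysis was possible because the samples form 1 group.

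The deposited files gave, per sample, 2 peak lists, a list of sites and a list of footprints on the mouse build mm10. Column 7 of the deposited peak lists holds the signal at the peak. All its values were whole multiples of a step of 0.00508 in replicate 1 and 0.00559 in replicate 2 (tolerance 0.05 steps); such steps would fit a density of cuts scaled to read depth, but the scale is not stated, so signals are in the authors' unit and the depth is unknown. Because each list was scaled separately, ratios of signals between replicates are given relative to the median of all genes and describe the files only. The p-value type column of the deposited site files is a false discovery rate under 0.05, with no count or cut rate. In the deposited footprint files the same p-value type column is a constant 0.01, a threshold and no measurement. Per the deposited descriptions, peaks, sites and footprints were made per sample from the filtered alignments. The caller, the aligner and their versions were not given in the sources used here. Every peak of the larger list overlapped a site with a rate under 0.05, and every peak of the smaller list a site under 0.001; these are called the inclusive and the strict list, and the inclusive list was used. It held 131398 and 91567 peaks (26.4 and 18.4 Mb, median width 200.0 bp, median signal 0.599 and 0.760), the strict list 86830 and 57869, and the footprint files 339656 and 234091 footprints of median 10 bp. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only, except those of log2 ratios and rank differences between replicates. The latter are 95% bootstrap intervals over genes or regions and do not cover the spread between samples. Both alleles were read against the reference genome, and alleles were not separated.

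Genes were the 21911 protein-coding genes of GENCODE M21, 1 per symbol, with every annotated protein-coding start site. A promoter was 1000 bp on either side of a start site, and a gene body was taken with 2 kb on both sides. The 27 gene lists, 23 motif consensus sequences, comparisons and most alternatives were fixed before the data were examined. The lists were fast fibre, slow fibre, shared sarcomere and excitation, developmental fibre, myogenic regulators, neuromuscular junction, atrophy and denervation, glycolysis and glycogen, mitochondrial and oxidative, circadian clock, senescence and ageing, hindlimb position, anterior position and housekeeping. Cell type lists were satellite cell, fibro-adipogenic and fibroblast, endothelial, mural, macrophage and immune, Schwann cell, tenocyte, adipocyte and erythroid, with neuron, liver, heart and germ cell as tissues the sample should not hold. Bmal1 was not in the annotation, which names this gene Arntl, also on the list. Myf5, Myog and Chrng are each on 2 lists. The share of promoters with a peak was set against 10000 random lists matched on promoter CpG content in 10 strata, and peaks per 10 kb of gene body against 10000 lists matched on gene length. A list was said to stand apart only where both replicates were above percentile 97.5 or below percentile 2.5. The share of promoter bases past a rate of 0.05 replaced a cut rate, which the files lack.

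Named genes followed a rule. From each list these were the 2 members whose strongest promoter peak had the highest mean rank over both replicates, and up to 2 members with no promoter peak in either. Genome-wide they were the 10 genes with the highest promoter rank, the 10 with the most shared body peaks and the 5 longest regions called in both. Some genes that the rule names, and 1 motif, are not reported here. Genes named outside the rule are said to have been chosen after their values were seen, except Dmd and Phka1, given as members of fixed lists on the X chromosome.

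Peaks overlapped when they shared at least 1 bp. Chance overlap came from 100 random placements on the same chromosome, and for footprints from 100 placements inside the same peaks. Motifs were searched on both strands in footprints and in equally wide windows of the same peaks outside footprints, with the myogenic E-box as CAGCTG, the general E-box as CACGTG, AP-1 as TGASTCA, MEF2 as YTAWWWWTAR, SP/KLF as GGGCGGGG, FOX as TGTTTAC, GATA as AGATAA and RUNX as TGTGGTT. A motif was above or below its control only where the 95% interval of the ratio left out 1 on the same side in both replicates.

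Alternatives were other promoter windows (500 and 2500 bp), only the 5′-most start site, unmatched random lists, a flank of 10 kb, the better 50% of the peaks, runs of adjacent sites as regions, the same number of top peaks, a reciprocal overlap of 50%, whole footprints inside peaks, footprints inside peaks of both replicates, footprints widened by 5 bp, distal or promoter footprints alone, dinucleotide-shuffled footprints, ranks, Pearson correlation, counts per gene and leaving out each replicate. The strict list, the same number of top peaks for gene lists and windows matched on G and C content were added after the data were seen.

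The procedures were tested on simulated data. A planted overlap of 51.1% was recovered as 51.0%, and 400 of 400 peaks matched an all-against-all search. Among 200 simulated lists of 13 genes, 0% were called with no shift, 14% when open promoters were raised by 20 points and 66% at 40 points. The 2 simulated replicates were drawn independently, while most promoters open in 1 real replicate were open in both. These call rates therefore do not carry over to the real lists. Planted motifs were found in 100% of windows, which only checks the search, since exact copies of the consensus were planted. Simulated footprints and control windows had the same base composition, so a difference in G and C was not simulated. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used, with random seed 1.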

Results

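The promoters that build and fuel the fast muscle fibre were open in the calf muscle (gastrocnemius) of old male mice. Actn3, whose product anchors actin at the Z-disc of fast fibres (chromosome 19, 4861216 to 4877909), carried a promoter peak with a signal of 6.06 in replicate 1 and 6.47 in replicate 2. Mybpc2, the fast form of myosin-binding protein C (chromosome 7, 44501699 to 44524656), had signals of 5.83 and 5.09. Both peaks lay upstream of the gene records (4878441 to 4878740 for Actn3 and 44525161 to 44525400 for Mybpc2 in replicate 1). Whether neighbouring genes share these peaks was not examined. All 16 genes of the fast fibre list had a promoter peak in replicate 1 and 13 had one in replicate 2, a mean of 90.6% ± 13.3 (SD, n = 2). The 3 exceptions, chosen after their values were seen, were Myh1, Myh2 and Myh4, which encode the adult fast myosin heavy chains. Their peaks in replicate 1 had signals of 0.386, 0.340 and 1.38, against a median of 0.599 over all peaks of that replicate.

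Shared parts of the contractile apparatus were open throughout. All 16 promoters of the shared sarcomere and excitation list had a peak in both replicates, where matched random lists had a median of 50%. Des, which encodes the desmin filament that ties neighbouring myofibrils together (chromosome 1, 75360329 to 75368579), had signals of 5.32 and 4.57. Jph1, which holds the T-tubule against the calcium store, had 3.66 and 3.65. The slow fibre list was open at 10 and 8 of 13 promoters, at percentiles 99.6 and 96.0 of its random lists, so it did not stand apart in both. Its strongest promoters were those of Tpm3, which encodes slow tropomyosin, with 5.10 and 4.73, and Atp2a2, the slow calcium pump, with 2.42 and 2.96. The Tpm3 peak (chromosome 3, 90079401 to 90079660 in replicate 1) lay at a start site inside the gene record, 90072649 to 90100902. Which Tpm3 transcript uses that start site was not examined, so the peak need not belong to the slow form. Myh7, the slow myosin heavy chain, had no peak at its promoter or in its body in either replicate. Tnni1, slow troponin I, had no promoter peak but 6 and 7 peaks in and around its body. With a promoter window of 2500 bp, or with runs of adjacent sites as regions, the slow fibre list passed the upper limit in both replicates, and with random lists not matched on CpG content the fast fibre list fell to percentile 92.9 in replicate 2.

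Energy supply was open in full. All 13 promoters of the glycolysis and glycogen list and all 15 of the mitochondrial and oxidative list had a peak in both replicates. Gys1, muscle glycogen synthase (chromosome 7, 45434844 to 45456619), had signals of 12.6 and 15.1, and Pkm, pyruvate kinase, had 7.51 and 6.72. Esrra, a nuclear receptor that switches on genes of oxidative metabolism (chromosome 19, 6910977 to 6921813), had 14.04 and 14.81, and Cs, citrate synthase, had 7.61 and 7.68. Both lists stayed above their random lists under every alternative tried for promoter lists.

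Regulators of muscle identity were open as well, though their promoters are CpG-rich and open in most random lists too. Of the 11 myogenic regulators, 10 had a promoter peak in both replicates, at percentiles 81.1 and 85.4. Srf, which drives actin genes, had signals of 6.75 and 6.99, and Mef2a, which acts with the MyoD family, had 6.51 and 7.31. Myf5, which starts the muscle programme in embryos and marks satellite cells, had no peak in either. The neuromuscular junction list was open at 11 and 10 of 12 promoters and stood above its random lists. Etv5, which directs transcription in the nuclei under the synapse, had 8.71 and 8.07. Chrnb1, the beta subunit of the acetylcholine receptor, had 6.26 and 5.90, and Chrnd, its delta subunit, had no peak. The junction list was no longer above the limit in both replicates with a promoter window of 500 bp (percentile 93.7 in replicate 2) or 2500 bp (95.9), with the 5′-most start site alone (97.3) or against unmatched random lists (91.8).

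Genes that rise when muscle wastes or ages did not form a uniform group. The atrophy and denervation list was open at 9 and 8 of 10 promoters, at percentiles 92.2 and 78.5. Foxo3, a driver of protein breakdown, had signals of 7.96 and 8.22, and Klf15, which links glucocorticoids to amino acid use, had 6.86 and 7.57. Chrng, the fetal acetylcholine receptor subunit that returns after denervation, had no promoter peak. The senescence and ageing list was open at 10 and 9 of 11 promoters, at percentiles 99.6 and 97.8. Trp53 (p53) had 6.44 and 6.85, and Cdkn2b, an inhibitor of the cell cycle, had 5.63 and 5.77, while Mmp3, a secreted protease, had none. The peaks of Foxo3 (chromosome 10, 42277621 to 42277900) and Trp53 (chromosome 11, 69579281 to 69579560 in replicate 1) lay upstream of the gene records. Whether neighbouring genes share them was not examined. No younger animals were measured, so no value here is a change with age, and the senescence list was no longer above the limit in replicate 2 against unmatched random lists (percentile 89.3), with the better 50% of the peaks (96.6), with runs of adjacent sites (97.1) or with the 5′-most start site alone (95.9).

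The clock was open at every promoter. All 12 circadian genes had a peak in both replicates, at percentiles 95.7 and 96.7, below the limit because CpG-matched random lists reached a median of 83.3%. Nr1d2 and Nr1d1, the REV-ERB repressors of the clock, had signals of 12.24 and 11.96 and of 10.3 and 11.5. The housekeeping list was open at all 14 promoters, led by the ribosomal protein genes Rplp0 with 13.1 and 16.3 and Rpl13a with 8.85 and 9.36. The developmental fibre list was open at 2 and 1 of 5 promoters. Myl4, an embryonic and atrial myosin light chain, had a strong peak of 10.5 and 11.3, while Myh8, perinatal myosin, had 0.249 in replicate 1 alone. Myh3, embryonic myosin, and Actc1, cardiac actin, had none. The circadian list passed the upper limit in both replicates with the better 50% of the peaks, with the strict list or against unmatched random lists. The housekeeping list fell to percentiles 91.8 and 94.2 with the 5′-most start site alone and to 97.4 in replicate 1 with a window of 2500 bp.

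Genes that mark position along the body and limb were open in part. Hoxc10 (chromosome 15, 102966796 to 102971893) and Hoxa10, which pattern the hindlimb, had signals of 6.67 and 6.37 and of 3.599 and 3.349. Pitx1, which specifies the hindlimb in the embryo, had no peak at its promoter or in its body. The hindlimb position list was open at 8 of 10 promoters in each replicate, at percentiles 17.1 and 20.0. The anterior position list was open at 6 and 5 of 10 promoters, at percentiles 7.65 and 2.21. Hoxa3 had 1.93 and 1.63, and Hoxa2 and Hoxb1, which pattern the hindbrain, had none. The Hoxa3 peak (chromosome 6, 52213021 to 52213460 in replicate 1) lay at the start of a record, 52169062 to 52213336, that spans Hoxa4, Hoxa5 and Hoxa6. It may not belong to Hoxa3 alone, although it counts as open in the anterior list. The anterior list fell below the lower limit in both replicates when the same number of top peaks or the strict list was used, with 45.0% and 35.0% of promoters open on average.

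**Figure D1:**
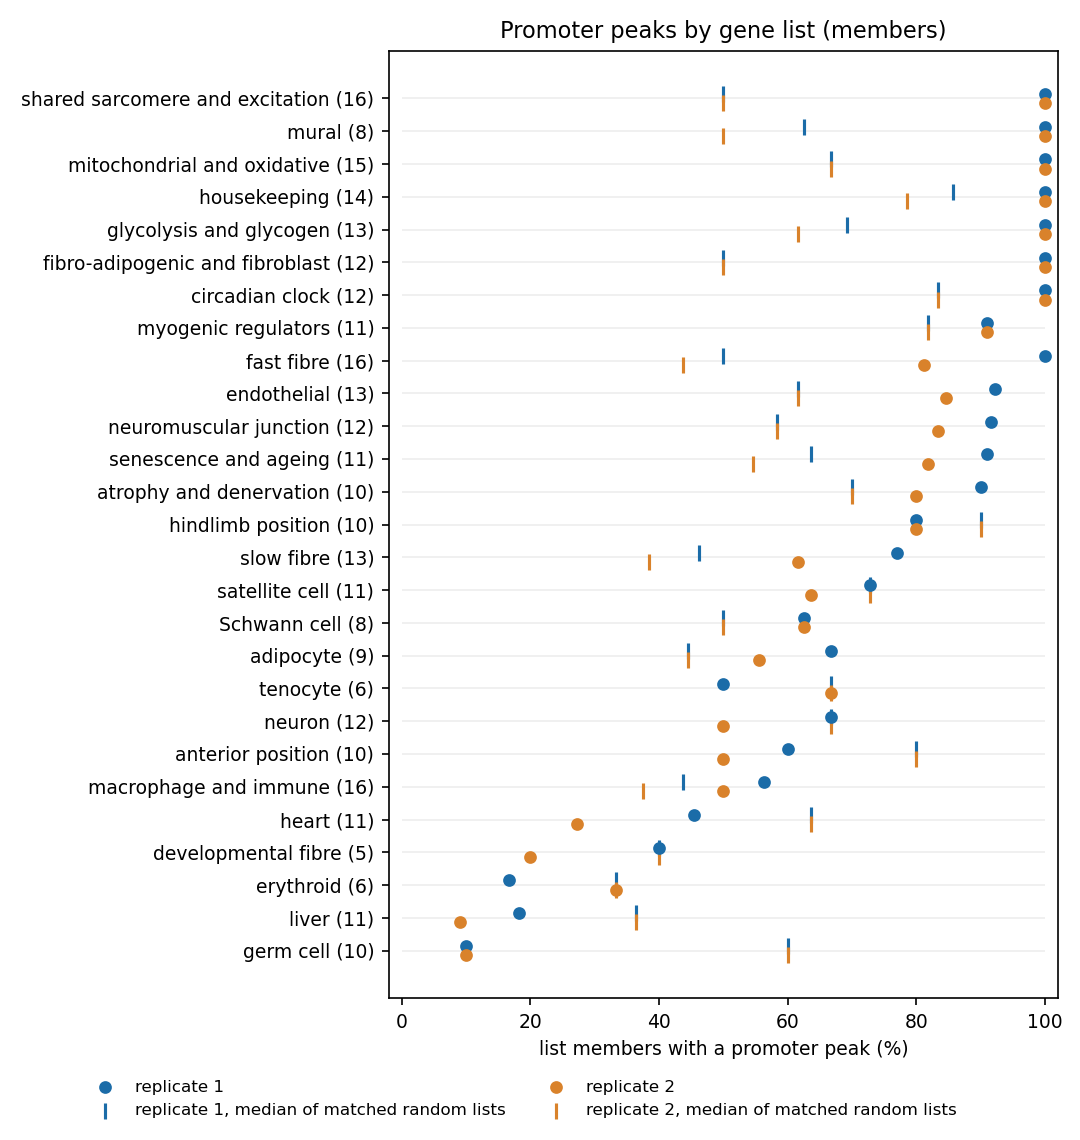
Share of each list's members with a promoter peak in percent (x axis) for the 27 gene lists (y axis, number of members in brackets), with points for the 2 replicates and vertical ticks for the median of matched random lists. The shared sarcomere list lies at 100% in both replicates against random medians of 50%, and the germ cell list at 10.0% against 60%.

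Genes of cells that lie between the muscle fibres were open too. All 12 promoters of the fibro-adipogenic and fibroblast list had a peak in both replicates, against a random median of 50%. Col1a1, a chain of type I collagen, had signals of 4.54 and 4.47, and Gsn, gelsolin, had 2.58 and 3.23. All 8 mural promoters were open, with Myh11, smooth muscle myosin, at 1.83 and 1.89 and Pdgfrb, the PDGF receptor of pericytes, at 1.57 and 1.89. The endothelial list was open at 12 and 11 of 13 promoters, led by the junction protein gene Esam with 1.51 and 1.84 and the secreted vessel factor gene Egfl7 with 1.01 and 1.38. The satellite cell list, of muscle stem cells, was open at 8 and 7 of 11 promoters, at percentiles 47.5 and 29.7. Spry1, a brake on growth factor signalling in quiescent stem cells, had 7.04 and 8.78, and Sdc4, a cell surface proteoglycan, had 2.84 and 3.57. Pax7, the satellite cell regulator, had no promoter peak but 9 and 6 peaks in and around its body. The endothelial and mural lists were not above the limit in both replicates when the better 50% of the peaks was used, with 57.7% and 68.8% of promoters open on average, nor with a promoter window of 500 bp or the strict list. The endothelial call also ended with the 5′-most start site alone, the same number of top peaks and unmatched random lists.

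Lists of other cell types were open in part. The macrophage and immune list was open at 9 and 8 of 16 promoters, at percentiles 89.9 and 86.3. Spi1 (PU.1), the regulator of macrophage fate, had signals of 0.660 and 1.12, and Cd68, a lysosomal protein of macrophages, had 0.731 and 0.906. Ptprc (CD45) and Csf1r, the receptor for macrophage growth factor, had no promoter peak. Of 8 Schwann cell promoters 5 were open in each replicate. Egr2, which switches on myelin genes, had 4.42 and 4.36, and Sox10, the regulator of Schwann cell fate, had none. The tenocyte list was open at 3 and 4 of 6 promoters, with the tendon regulators Mkx at 1.17 and 1.24 and Scx at 0.965 and 1.22, and without Tnmd and Fmod. The adipocyte list was open at 6 and 5 of 9, with Lpl, lipoprotein lipase, at 1.31 and 1.54 and Plin1, the lipid droplet coat protein, at 0.827 and 1.26, and without Cidec and Cfd. The erythroid list was open at 1 and 2 of 6, with Klf1, the erythroid regulator, at 0.531 in replicate 2, and the globin genes Hba-a1 and Hbb-bs had none. These lists hold 6 to 16 genes, and none of the 5 stood apart in both replicates.

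Promoters of germ cell, liver and heart genes were mostly closed, but those of neuronal genes were not. Of these lists only that of germ cells stood apart from its random lists in both replicates. Only Dazl, an RNA-binding protein of germ cells, was open among 10 germ cell genes, with signals of 3.80 and 4.29, and this list lay below its random lists in both replicates. Ddx4, a germ cell helicase, and Sycp3, a part of the meiotic chromosome axis, had no peak at all. The liver list was open at 2 and 1 of 11 promoters, with Apob, the carrier of lipoproteins, at 0.706 and 0.727 and Pck1, which feeds gluconeogenesis, at 0.315 in replicate 1. Alb, albumin, and Apoa1 had no promoter peak. Heart genes were open at 5 and 3 of 11 promoters, at percentiles 6.09 and 0.115. Ryr2, the cardiac calcium release channel, had 0.574 and 0.475, and Nppa and Myh6 had none. Neuronal genes were open at 8 and 6 of 12 promoters, at percentiles 42.6 and 10.1. Camk2a, a synaptic kinase, had 2.27 and 1.79, Rbfox3 (NeuN) had 1.497 and 1.968, and Neurod6 and Slc17a7 had none. The germ cell list was no longer below the limit in both replicates with a promoter window of 2500 bp, where 40.0% were open. With a window of 500 bp the neuron and liver lists fell below it (29.2% and 4.55% open on average), as did the heart list with the better 50% of the peaks (9.09%) or the 5′-most start site alone (18.2%) and the liver list against unmatched random lists.

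Across the genome Dynlt1b, a dynein light chain (chromosome 17, 6430112 to 6436296), had the promoter peak of highest rank, with signals of 33.4 and 42.6, followed by Hjurp, the chaperone of centromeric histone, with 25.5 and 27.3. Dnpep, an aminopeptidase next to Des, had 16.7 and 20.2, and Add3, an adducin of the membrane skeleton, had 15.5 and 20.0. Sugct and Mplkip shared a single promoter peak of 15.9 and 18.8, and Acin1 and 1700123O20Rik shared a single peak of 14.7 and 18.1. Sde2, a telomere and splicing factor, had 15.2 and 16.7, and Leprot, which shares its start region with the leptin receptor, had 14.3 and 18.2. Of 21911 protein-coding genes, 14335 (65.4%) had a promoter peak in replicate 1, 13871 (63.3%) in replicate 2 and 13622 (62.2%) in both. Dynlt1b has close paralogs nearby, and mappability was not tested.

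The bodies and flanks of several muscle lists, and of some others, held more peaks than random lists. Myogenic regulators had a median of 5.603 and 3.922 peaks per 10 kb of gene body with 2 kb on both sides, against 0.697 and 0.476 in random lists matched on gene length. The fast fibre list had 4.46 and 2.78, atrophy and denervation 4.32 and 2.11, and glycolysis and glycogen 3.74 and 2.75. Hindlimb position had 4.06 and 3.76, mitochondrial and oxidative 2.87 and 2.09, circadian clock 2.66 and 1.74, and senescence and ageing 2.76 and 2.03. Housekeeping had 2.54 and 2.36, mural 1.983 and 1.497, fibro-adipogenic and fibroblast 1.91 and 1.32, and shared sarcomere and excitation 1.70 and 1.24. These 12 lists stood above their random lists in both replicates and 0 of 27 stood below. The counts include promoter peaks, and these random lists were not matched on CpG content. They therefore do not show an excess of peaks beyond promoters. The neuromuscular junction list (2.08 and 1.17), the slow fibre list (1.57 and 0.939) and the endothelial list (0.9501 and 0.6044) were not above in both, and the erythroid and germ cell lists had medians of 0. With a flank of 10 kb the atrophy list fell to percentile 93.2 in replicate 2 and the senescence list to 88.0 in replicate 1, while the junction list was above in both. With the strict peak list the hindlimb and mural lists were no longer above in both, nor was the mural list with the better 50% of the peaks.

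Some muscle genes differed widely in body peaks between the replicates, and these were chosen after their values were seen. Myh4, the IIb fast myosin that dominates mouse calf muscle (36 peaks in replicate 1, 1 in replicate 2), Ckm, muscle creatine kinase (22 and 8), and Fbxo32, the atrogin-1 ubiquitin ligase (22 and 4), had more in replicate 1. Ttn, the giant spring of the sarcomere (24 and 54), and Cpt1b, which brings fatty acids into mitochondria (3 and 13), had more in replicate 2. Many of these were weak peaks in dense clusters called in replicate 2 alone. Ttn had clusters of 5, 11 and 21 such peaks (median signals 0.229, 0.224 and 0.190). Cpt1b had 1 of 7 peaks (0.291), against a median of 0.760 over all peaks of replicate 2. Myh4, Ckm and Fbxo32 also had clusters called in replicate 1 alone. Among all genes, the regulators Rora, a nuclear receptor of clock and metabolism, with 61 shared body peaks, and Camta1, a calmodulin-binding activator, with 48, were among the 10 with most. Gse1 had 69, Sh3pxd2a, a scaffold of cell invasion, 58, Tns1, a link between integrins and actin, 51, Wwox 47 and Arhgap26 43. The records of Gm20388 (440), Fgfr2 (169) and Gm37240 (55) span neighbouring genes, so those counts do not belong to a single gene.

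Of the 27 lists, the circadian clock had the widest open stretches at its promoters in both replicates. The median share of promoter bases past a false discovery rate of 0.05 was 82.8% and 70.6% for the circadian list and 79.9% and 51.7% for the atrophy list, against 29.9% and 26.1% over all genes. Glycolysis reached 69.8% and 57.1%, housekeeping 64.2% and 57.0%, myogenic regulators 61.6% and 63.5%, and mitochondrial genes 49.7% and 47.6%. The fast fibre list had 46.4% and 36.9%, senescence 46.7% and 42.2%, and shared sarcomere 39.8% and 36.3%. These 9 of 27 lists were above all genes in both replicates, and the developmental fibre, erythroid, liver and germ cell lists had medians of 0. The longest stretches open in both replicates were 4261 bp over Brd2, a reader of acetylated histones, and H2-DMa (chromosome 17, 34118750 to 34123010), 4179 bp over Jun, a subunit of AP-1 (chromosome 4, 95049920 to 95054098), and 4143 bp over Myc (chromosome 15, 61984215 to 61988357). The next were 3693 bp over Pcdh7, a protocadherin (chromosome 5, 57716425 to 57720117), and 3638 bp over Ppp2r3d, a phosphatase subunit (chromosome 9, 124422466 to 124426103).

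Promoter peaks of Esrra, Gys1 and Des were called in both replicates, while that of Myh4 was called in replicate 1 alone. Strong sites were mostly shared and weak sites often were not. Of 91567 peaks of replicate 2, 76513 (83.6%, exact 95% interval 83.3 to 83.8) overlapped a peak of replicate 1. Of 131398 peaks of replicate 1, 76733 (58.4%, 58.1 to 58.7) overlapped a peak of replicate 2. Peaks moved to random places on the same chromosome overlapped in 2.11% and 1.47%. By quintile of signal, the shared share rose from 14.9% to 98.9% in replicate 1 and from 41.4% to 99.7% in replicate 2. The Jaccard index of covered bases was 45.7%. Signals had a Spearman correlation of 0.716 across 142555 regions of the union, which are not independent replicates, and 0.915 across the 74212 called in both. In the latter the median log2 ratio was 0.02, and 97.1% of regions were within 2-fold. With the same number of top peaks, 75.4% were shared in each direction, and the Pearson correlation of log2 values over the union was 0.344. In both correlations over the union, a region without a peak in a replicate was entered as having no signal there. Those correlations therefore partly reflect whether a peak was called.

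**Figure D2:**
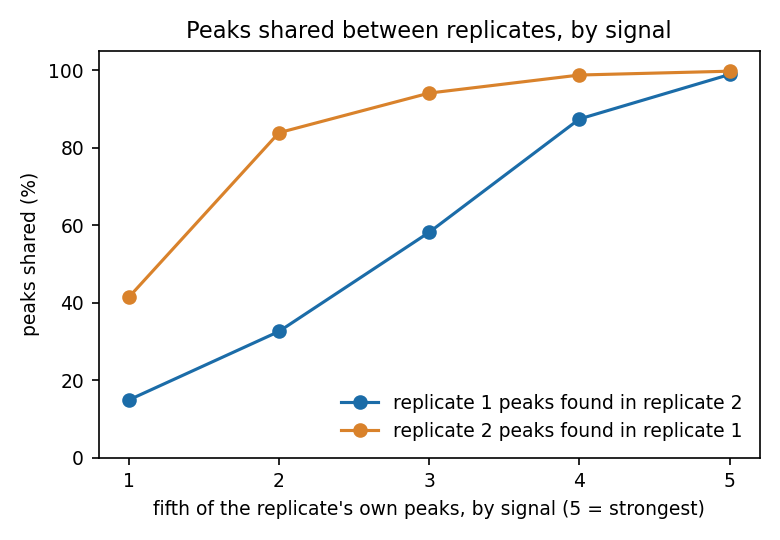
Share of peaks that overlap a peak of the other replicate in percent (y axis) by quintile of peak signal (x axis), for the 2 replicates. The share rises from 14.9% to 98.9% in replicate 1 and from 41.4% to 99.7% in replicate 2.

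Gene promoters such as those named above took up a far larger part of the peaks than of the genome. Within 1000 bp of a protein-coding start site lay 21.8% of peaks in replicate 1 and 27.6% in replicate 2, a mean of 24.7% ± 4.08 (SD, n = 2), against 2.84% and 2.87% after random placement. Introns held 34.4% ± 3.40, exons 4.88% ± 0.206 and the space outside genes 36.0% ± 0.894 (SD, n = 2). The replicate with more peaks had the lower share at promoters.

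On the X chromosome, which these males carry once and which holds the muscle genes Dmd (dystrophin) and Phka1 (a subunit of muscle phosphorylase kinase), peaks were sparse. There were 22.1 peaks per Mb on X against 53.3 on the autosomes in replicate 1, and 14.2 against 37.2 in replicate 2, a mean ratio of 0.398 ± 0.0229 (SD, n = 2). The Y chromosome had a mean ratio of 0.0283 ± 0.0117. Per protein-coding gene the X ratio was 0.595, and among the better 50% of the peaks it was 0.231 per Mb. Copy number, gene density and mappability were not separated.

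Footprints, the short protected stretches inside open sites, held more sites of several factors than equally wide windows beside them. The CTCF core, the site of the insulator protein, was in 4315 of 298369 footprints and 6 equally wide windows of the same peaks in replicate 1, and in 3394 and 6 of 204142 in replicate 2. The myogenic E-box, bound by MyoD and myogenin, had ratios of 1.61 and 1.68, a mean of 1.65 ± 0.0481 (SD, n = 2). NRF1, a regulator of nuclear genes for mitochondria, had 38.4 and 41.5, CRE, the site of CREB, 24.3 and 33.4, and SP/KLF, the GC box of promoters, 18.5 and 18.2. The general E-box, bound by clock and MYC factors, had 2.47 and 1.95, and ETS had 1.96 and 2.18. NFI (67 and 32 footprints) and REST, the repressor of neuronal genes (48 and 33), were above their controls, which held 0 and 0 and 0 and 1 sites. In promoter footprints the mean ratio of the myogenic E-box was 0.875, and of its sites in peaks 24.4% were footprinted in each replicate, inside the range of 10 permuted sequences (18.3% to 33.5% in replicate 1), as were sites of the general E-box (36.8% in replicate 1 within 16.9% to 44.5%, and 33.6% in replicate 2 within 16.2% to 45.2%). In windows matched on G and C the ratios fell to 7.26 and 7.04 for SP/KLF and to 19.4 and 20.4 for NRF1, and against dinucleotide-shuffled footprints to 4.78 and 4.66 and to 16.4 and 18.1, and ETS was not above in both replicates in distal footprints alone.

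Sites of several tissue factors were less common in footprints than in the windows beside them. FOX, the site of the forkhead family that includes FOXO3, had ratios of 0.117 and 0.0625, and GR/NR3C, the glucocorticoid receptor site, 0.214 and 0.138. PU.1 had 0.299 and 0.219, GATA 0.426 and 0.301, and RUNX 0.695 and 0.790. FOX sites in peaks were footprinted in 9.47% and 8.61%, inside the range of permuted sequences (8.79% to 16.2% and 8.36% to 15.6%). Sites of GR/NR3C, PU.1, GATA and RUNX were also inside their permuted ranges in both replicates. MEF2, the partner of MyoD in muscle genes, had 0.915 and 0.319, and AP-1, the site of JUN and FOS, 1.17 and 0.785, so neither was on the same side of 1 in both replicates beyond counting error. SRF, NFY, ERR, TEAD and YY1 were not apart from their controls in both replicates, with mean ratios of 0.752, 1.04, 0.642, 0.726 and 1.74, and HNF1, a liver factor, had 0 sites. Footprints were richer in G and C than the windows (60.3% against 53.4% and 63.8% against 55.6%), and against dinucleotide-shuffled footprints the mean ratio of MEF2 was 6.91, of AP-1 2.11 and of NFY 1.60, with no motif below its control. In windows matched on G and C the sites of RUNX and GATA were no longer below in both replicates, while AP-1 (1.61 and 1.22) and NFY (1.32 and 1.18) were above, and in footprints widened by 5 bp AP-1 (1.39 and 1.11), NFY (1.26 and 1.17) and YY1 (1.81 and 2.05) were above, RUNX was no longer below, and MEF2 had 1.26 and 0.678; RUNX was not below in distal footprints or GR/NR3C in promoter footprints.

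**Figure D3:**
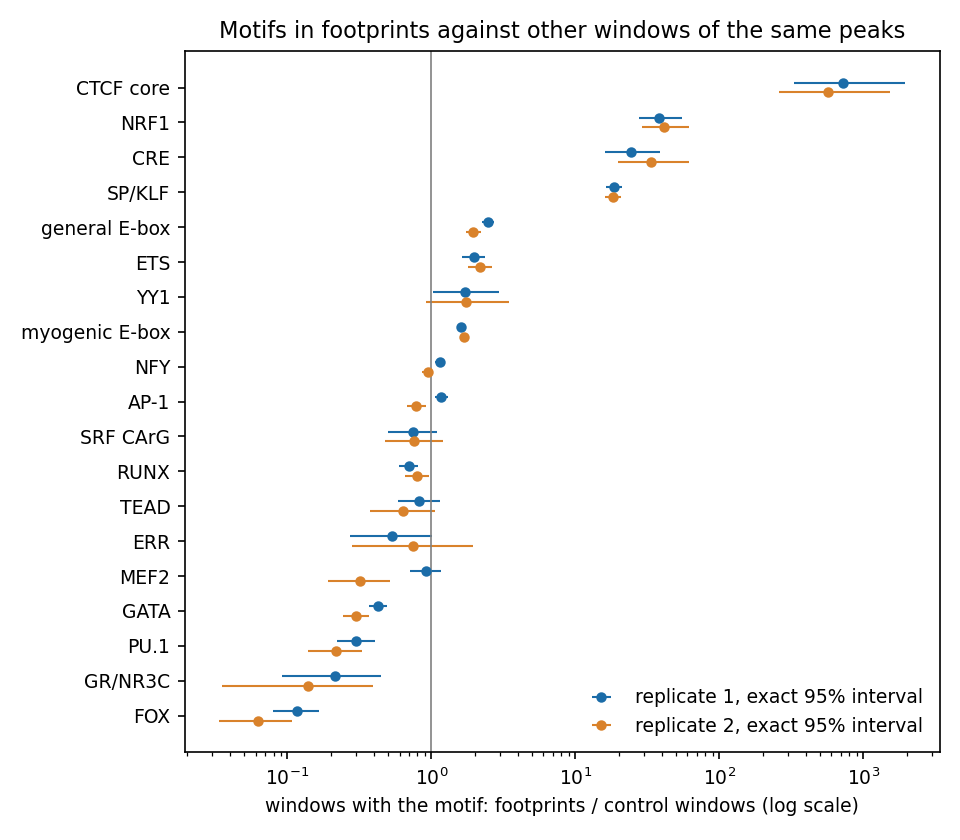
Ratio of the share of footprints with a consensus to that of control windows (log axis) for each motif, with points for the 2 replicates and bars for the 95% counting interval; NFI, HNF1 and REST are left out because a control held no site, and 1 motif is not drawn. CTCF lies at 719 and 566 and FOX at 0.117 and 0.0625.

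The share of distal peaks with a motif differed between shared and unshared peaks, and for MEF2 its direction differed between replicates. MEF2 sites were in 3.18% of shared distal peaks of replicate 1 and in 3.48% of its unshared ones, but in 2.42% and 0.743% in replicate 2. AP-1 sites were in 9.02% and 6.92% in replicate 1 and in 7.90% and 3.38% in replicate 2. The myogenic E-box was in 25.1% of shared and 16.1% of unshared distal peaks of replicate 1, and in 22.9% and 12.7% in replicate 2. Shared distal peaks were wider (221.4 and 194.5 bp on average) than unshared ones (160.0 and 158.4 bp), and the shares are not corrected for width.

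Footprints of the replicates overlapped more often than random placement in the same peaks gave. Of 234091 footprints of replicate 2, 61.5% (exact 95% interval 61.3 to 61.7) overlapped a footprint of replicate 1, and of 339656 of replicate 1, 41.6% (41.4 to 41.7) overlapped a footprint of replicate 2. Inside peaks the values were 62.6% and 42.2%, against 39.6% and 27.3% when footprints were placed at random in the same peaks. Of all footprints, 89.5% and 89.0% lay in a peak of their own replicate.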

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

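The strict list, the same number of top peaks for gene lists and the windows matched on G and C were chosen after the results were seen. Depth is not stated in the files, so its effect on the number of peaks could not be measured. A stricter footprint list and the highest site value per promoter were not run, because the files give no footprint score and no cut rate. For changes listed here the cause was not tested.

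A reciprocal overlap of 50% lowered shared peaks to 69.7% (replicate 2 in replicate 1) and 48.6% (replicate 1 in replicate 2), and shared footprints to 45.1% and 31.1%. Footprints inside peaks of both replicates were shared in 67.8% and 59.0%. With the better 50% of the peaks, shared peaks were 96.4% and 67.6%, the promoter share 33.6%, the X ratio 0.231 and the Y ratio 0.00904. The same number of top peaks gave 75.4% in each direction. Runs of adjacent sites gave 72.8% and 36.4%, and held 99.5% of footprints; whole footprints lay inside peaks in 86.5%. The strict list gave 87.2% of replicate 2 shared, a promoter share of 30.2%, an X ratio of 0.365 and a Y ratio of 0.0161. Per protein-coding gene the X and Y ratios were 0.595 and 0.118. The correlation of signals was 0.344 as Pearson of log2 values and 0.915 in regions called in both. Promoter windows of 500 and 2500 bp gave promoter shares of 20.2% and 30.4%.

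Of 10 gene lists above their random lists at promoters, 6 were above with the 5′-most start site alone. Lists below, 1 in the main setting, were 3 with a window of 500 bp and 0 with 2500 bp, and 2 each with the better 50%, the 5′-most start site, the strict list, the same number of top peaks and unmatched random lists. Leaving out 1 replicate gave 1 to 3 lists below at promoters and 1 in gene bodies in each case, where both replicates together gave 0. For single lists, 234 of the comparisons at promoters stayed the same, 21 lost their call and 15 gained one. In gene bodies these were 152, 5 and 5. Lists that had no call and gained none count as the same. Leaving out a replicate is included, although it could not lose a call that both replicates had to pass. These totals therefore do not measure how often a call survived.

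Dinucleotide-shuffled footprints raised the motifs above their control from 9 to 14 and lowered those below from 6 to 0. Among reported motifs that had been apart from their control, the mean ratio turned above 1 there for RUNX (1.59) and PU.1 (1.04), and for RUNX in windows matched on G and C (1.07), where 3 motifs were below. The myogenic E-box turned to 0.875 in promoter footprints. For single motifs 106 comparisons stayed the same, 8 lost their call and 13 gained one. Here too, motifs without a call count as the same, and leaving out a replicate could not lose a call.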

Other observations

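All tests in this part, and the Hox genes, were chosen after the patterns they bear on were seen; only for the overlap with the strict list and for the MEF2 ratio in windows matched on G and C was the expected outcome written before that test's own value was seen. An expectation set for endothelial and immune genes jointly was not met and was split after its result was seen. With 1 group in the design, no biological explanation that needs a contrast between groups was tested.

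Promoter peaks of the Hox genes, which fix position along the body axis, were counted by cluster without a test of the differences. In the Hoxa cluster 8 of 11 promoters had a peak in both replicates, with Hoxa7 at a signal of 4.77 and 5.75. In the Hoxb cluster 2 of 10 did, and 6 had no peak in either, among them Hoxb9 and Hoxb13. The Hoxc cluster was open at 4 of 9 promoters, led by Hoxc10 with 6.67 and 6.37 and Hoxc13 with 2.03 and 2.70, and the Hoxd cluster at 5 of 9. By paralog group, 6 of 12 promoters of groups 1 to 4 were open in both replicates, 5 of 11 of groups 5 to 8, 6 of 10 of groups 9 to 11 and 2 of 6 of groups 12 to 13. The records of Hoxa3, Hoxc5 and Hoxd3 span neighbouring Hox genes, so the counts by paralog group may include peaks of neighbours.

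Promoters of several muscle lists were stronger in replicate 1 and endothelial promoters in replicate 2: relative to all 12990 genes with overlapping promoter peaks (median log2 ratio of replicate 1 to replicate 2 of -0.10), medians were 0.58 for shared sarcomere (14 of 14 higher), 0.49 for fast fibre (10 of 10), 0.26 for neuromuscular junction (8 of 9), 0.25 for mitochondrial (13 of 14) and -0.69 for endothelial genes (8 of 9 lower), while slow fibre (0.14) and myogenic regulators (0.15) had intervals that held 0, and mural genes (0.29, 6 of 7 higher) were at percentiles 90.5 by ratio and 80.4 by rank of matched lists and immune genes (-0.44, 5 of 6 lower) at 1.01 and 7.17. By rank the junction list had 7 of 9 genes higher, at percentile 99.7 of matched lists, but with an interval that held 0 (-0.29 to 10.1 percent). The tables argue against base composition or strength of the peaks. The sarcomere and endothelial medians differed by 1.27 (95% bootstrap interval over genes 0.75 to 1.41), where random lists matched on both properties reached 0.50 at their upper limit. These lists had the highest and lowest median ratios at promoters, while the random lists were not picked as extremes. Each set alone against its matched lists, sarcomere lay at percentile 99.99 and endothelial at 0. Endothelial and fibro-adipogenic medians differed by -0.73 (-1.003 to -0.19) at promoters and by -0.32 (-0.78 to -0.12) away from them. Endothelial and mural medians differed at promoters (-0.98, -1.22 to -0.32) and not detectably away from them (-0.11, -0.80 to 0.11). These lists thus did not all move alike. A lower share of muscle fibre nuclei in replicate 2 would move them alike only if their regions were equally closed in fibre nuclei. That was not measured, so these values cannot decide whether such a lower share is the whole difference. More endothelial nuclei in replicate 2 remains a candidate explanation: regions away from promoters at endothelial genes were also weaker in replicate 1 (-0.29, percentile 0.09 of matched lists), although the strongest promoters, Esam and Egfl7, reached only 1.84 and 1.38. More immune nuclei cannot be told apart from no change, since immune genes away from promoters lay at percentile 62.6 with an interval of -0.78 to 0.38.

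Dense clusters of peaks called in replicate 2 alone (at least 5 peaks with gaps of at most 1000 bp) numbered 394 and held 23.8% of its 15054 unshared peaks, against 109 clusters and 1.45% of 54665 in replicate 1. Calls near the false discovery threshold are argued against, since 72.6% (71.1 to 74.0) of the clustered peaks of replicate 2 overlapped the strict list, against 20.0% of its other unshared peaks. Weak signal itself is not argued against, because their median signal was 0.157, against 0.358 for other unshared peaks. Clustered peaks of replicate 1 also overlapped the strict list more often than its other unshared peaks (58.8% against 32.3%). More copies of these stretches in replicate 2 cannot be told apart: the 60 shared regions inside them had a median log2 ratio of replicate 1 to replicate 2 of 0.11 (0.01 to 0.22), but they lay in 50 of the 394 clusters and had to be called in replicate 1. As for open bodies of active genes, 53.8% of the replicate 2 clusters lay on a gene with a promoter peak, against at most 39.6% in 100 random placements. Clusters of replicate 1 also exceeded theirs (77.1% against at most 57.8%). All peaks of replicate 2 lay away from promoters and genes less often than after random placement (35.4% against 57.6%). This comparison therefore cannot decide whether gene bodies explain the replicate 2 clusters. Of these clusters 41.1% lay on no protein-coding gene, among them 6 of the 12 largest and the largest (37 peaks, chromosome 3, 3000361 to 3017200).

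The MEF2 site was no more common in footprints than in the windows beside them, with ratios of 0.915 and 0.319, although in footprints widened by 5 bp these were 1.26 and 0.678. Avoidance of this base composition whatever its order is argued against: 31.1% of 3916 MEF2 sites in peaks of replicate 1 overlapped a footprint, against at most 19.6% for 10 permuted consensus sequences, and in replicate 2 the values were 24.6% and 18.0%. Footprints richer in G and C than the windows may explain the low ratios, since windows matched on G and C gave a mean of 2.21 ± 1.05 (SD, n = 2). This cannot be told apart from no effect in replicate 2, where 22 footprints and 15 windows held the site and the interval of the ratio, 0.727 to 3.04, included 1.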
